A study of Mus musculus with 48 samples.

How the data were processed

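ATAC-seq libraries were made from lung tumors, liver metastases and a lymph node metastasis of mice with Trp53, Rb1 and p130 deleted, 18 with Ad-CGRP-Cre and 30 with Ad-CMV-Cre. Per the labels' protocols, lysed cells were incubated with Tn5 transposase and libraries were built with a modified Nextera kit. Bowtie2, MACS2, DESeq2 and build mm9 are named in the submitters' processing notes, without versions or roles. Read trimming, duplicate removal and any shift of reads for the Tn5 cut are not given in the sources used here. Titles of 15 libraries name them as re-analyses of earlier samples.

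The deposited files are 3 lists of summits, 1 list of merged peaks and 2 tables of comparisons. Per the labels, summits were called on merged libraries: a CMV pool (19 libraries, preparation batch 1), a CGRP pool (14 libraries, batch 2) and a mixed pool (15 libraries of both vectors, batch 3). The score column of the deposited summit lists was read as −log10 of the q-value from its smallest value of 1.30, and it ranks peaks within a list only. In the authors' merged list, all 114043 peaks are 501 bp long, centred on a summit of the same name and score, and none overlaps the next. The filter that reduced the summits to these peaks is not given in the sources used here.

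Both comparison tables hold the same peaks and the same mean normalised count, a signal that the authors averaged over libraries. The log2 fold changes and their SEs are the authors' values, and the deposited Wald score equals the log2 fold change divided by its SE within 5.78e-11. The p-values and adjusted p-values are the authors', per the file headers with the column names of DESeq2 results. The direction of each comparison (amplified over not amplified, liver over lung) rests on the names of the deposited tables. A second set of deposited columns was read from its values as a test against an absolute log2 fold change of 0.5. Covariates of the authors' fit are not given in the sources used here. A p was missing for 170 peaks in each table. An adjusted p was missing for 8922 peaks of the CGRP comparison, and these were left out of its counts. The tables hold 0 columns of per-library values, so library depth is unknown and no count model was fitted here.

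Groups were taken from the labels: 8 Nfib-amplified and 7 not amplified CMV libraries, and 11 lung tumors and 7 liver metastases with Ad-CGRP-Cre. The description of 1 CMV library in the not amplified group does not list the comparison table, so its place in the authors' fit is open. Amplified CMV libraries came from preparation batches 1 (2 libraries) and 3 (6), and the others likewise (2 and 5).

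The main tests, the rule for named sites and most alternatives were fixed before the data were examined; the closing section names those chosen later. A peak was called changed at the authors' adjusted p under 0.05. The change of a peak in the comparisons was contrasted by a two-sided z test, with the SE taken as the root of the summed squared SEs and Benjamini-Hochberg adjustment. Overlaps were tested with Fisher's exact test over peaks with an adjusted p in both tables and adjusted over 4 overlaps. Correlation intervals came from 1000 bootstrap draws of 5 Mb windows. Windows of 1 Mb with at least 10 peaks were compared with all circular shifts of the peak order of their chromosome. A summit counted as shared within 250 bp of a summit of another pool. Odds ratios by pool are Mantel-Haenszel estimates within deciles of mean count. Named sites are the 5 raised and 5 lowered peaks with the largest absolute log2 fold change among changed peaks with a mean count of at least the median of tested peaks (21.2), and the 5 windows with the highest and the 5 with the lowest median.

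The annotation at hand was of another build than mm9, so no gene was assigned to a peak. The planned gene lists, promoter shares and gene-level names were not analysed here, and coordinates are given in place of genes, 1-based.

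Tested on simulated data, the difference test recovered 4.00%, 22.5% and 40.0% of 200 peaks changed by a log2 of 1, 2 and 3 among 114043 peaks, with 11.1%, 4.26% and 4.76% of 9, 47 and 84 calls false. Recovery under this adjustment depends on how many peaks change, so these shares do not describe the test on the data, where 26660 peaks were called. The circular-shift test recovered 0% of 10 windows raised by a log2 of 3 among 1861, and the reordering test all 10. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Alternatives covered the thresholds, the adjustment, a mean count minimum of 20, centring, chromosomes and windows left out, summit distance and summit score.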

Results

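The series measured open chromatin by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into accessible DNA, in a mouse model of small cell lung cancer. Tumors arose after Cre recombinase deleted Trp53, Rb1 and p130. Cre was delivered by adenovirus under the broadly active CMV promoter (Ad-CMV-Cre) or under the promoter of CGRP, a peptide of neuroendocrine cells (Ad-CGRP-Cre). The series title names the cell type of origin as the question. Of 48 libraries, 33 fell into 4 groups: 8 CMV libraries with amplification of Nfib, a gene on mouse chromosome 4 that encodes the transcription factor nuclear factor I/B, 7 CMV libraries without it, 11 CGRP lung tumors and 7 CGRP liver metastases. The remaining 15 CMV libraries were marked by the submitters as low in enrichment and entered no comparison. Labels called the chromatin of all 8 Nfib-amplified CMV libraries hyperaccessible and of none of the 7 others. The 1 Nfib-amplified CGRP lung tumor was labelled hypoaccessible. Accessibility was compared at 114043 merged peaks of 501 bp on build mm9. The mean normalised count had a median of 21.2 and an upper quartile of 46.5. Sequencing depth per library is unknown here, since the tables hold the authors' fitted values and no value per library.

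In CMV tumors, chromatin differed widely with Nfib amplification. Of 113873 peaks tested, 39032 (34.3%) were more accessible in Nfib-amplified libraries and 13936 (12.2%) were less accessible, at an adjusted p under 0.05 in the authors' deposited table. Raised peaks had a median log2 fold change of 2.44 with a median SE of 0.74, a 5.43-fold difference. Lowered peaks had a median of -1.54 with a median SE of 0.46. The median over all peaks was itself shifted, at 0.60. Relative to that median, 22710 peaks were higher and 29095 lower, a balance that centring brings about in part by construction. Under the stricter deposited test against an absolute log2 fold change of 0.5, 21603 peaks were raised and 5280 lowered.

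The direction of change went with the mean count of the peak. This is in part built in, since the mean count is averaged over the libraries compared. A site open mainly in amplified libraries has a low mean. In the weakest decile of peaks by mean count, 20.1% were raised and 2.01% lowered. In the fourth decile, 41.0% were raised and 9.09% lowered. Among the strongest decile, 25.3% were raised and 23.9% lowered on the authors' scaling. That balance depends on the scaling: with 0.60 subtracted from every peak, 938 of the strongest peaks were higher and 6992 lower, and 984 of the weakest were higher and 506 lower. The median log2 fold change fell from 1.12 in the weakest decile to -0.02 in the strongest.

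**Figure D1:**
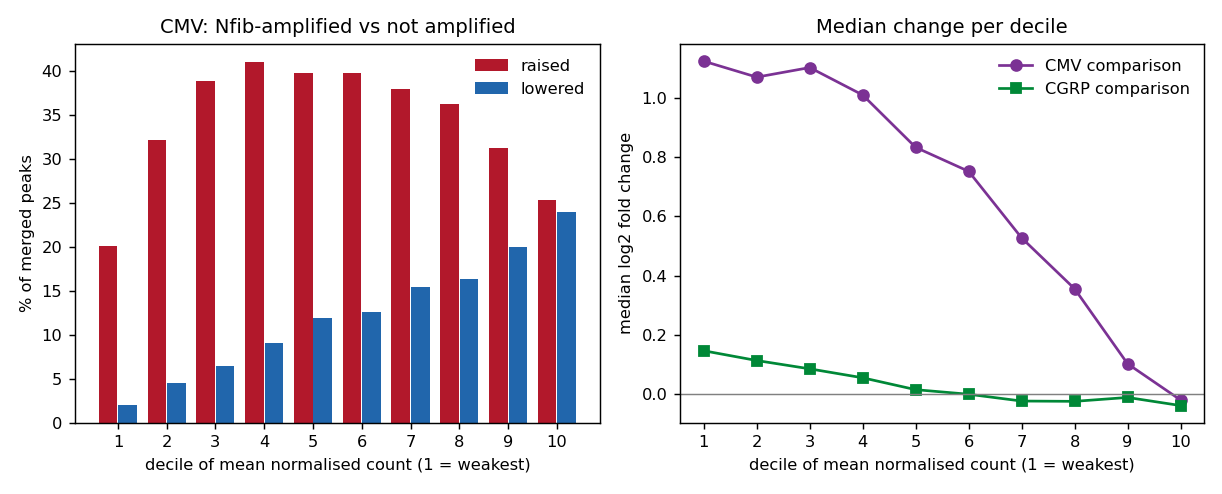
Left, percent of merged peaks raised (red) and lowered (blue) in Nfib-amplified against not amplified CMV libraries, by decile of mean normalised count from weakest to strongest. Right, median log2 fold change per decile for the CMV (circles) and CGRP (squares) comparisons. The CMV median runs from 1.12 in the weakest decile to -0.02 in the strongest, the CGRP median from 0.15 to -0.04. Part of the CMV gradient is built in, since the mean count is averaged over these same libraries.

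The peaks with the largest gains lay on different chromosomes. In the authors' deposited table, the top peak was on chromosome 3 from 74250093 to 74250593 (mm9), with a log2 fold change of 7.56 (SE 0.82, adjusted p = 2.141e-16) and a mean count of 35.6. The CGRP comparison gave the same peak -0.79 (SE 0.91, adjusted p = 0.858) in the authors' deposited table. Next in the authors' deposited table came chromosome 14 from 79582960 to 79583460 at 6.83 (SE 0.93), and chromosome 2 from 112634472 to 112634972 at 6.42 (SE 0.89). Chromosome 13 from 4330747 to 4331247 followed at 6.41 (SE 0.85) in the authors' deposited table, with chromosome 12 from 79199686 to 79200186 at 6.41 (SE 0.90). None of these 5 peaks passed the threshold in the CGRP comparison.

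On the authors' scaling, the largest losses were smaller on the log2 scale than the largest gains. Part of this gap goes with the median of 0.60 over all peaks. Chromosome 1 from 145967127 to 145967627 fell by 5.19 on the log2 scale (SE 0.59, adjusted p = 4.103e-15) in the authors' deposited table. Chromosome 10 from 84047402 to 84047902 fell by 5.18 (SE 0.67) in the authors' deposited table, and was also lowered in CGRP liver metastases, by a log2 fold change of -1.94 (SE 0.44, adjusted p = 0.003442). The authors' deposited table gave -5.15 (SE 0.50, adjusted p = 8.207e-20) on chromosome 9 from 72937038 to 72937538, the peak with the highest mean count of the 5 (90.7). Chromosome 16 from 55816366 to 55816866 had -5.15 (SE 0.76) and chromosome 8 from 102702422 to 102702922 had -5.12 (SE 0.75) in the authors' deposited table.

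Most megabases held both gains and losses. Of 1861 windows of 1 Mb with at least 10 peaks, 1600 held both raised and lowered peaks, where 100 random reorderings of the peaks of each chromosome, run after the data were seen, gave 1809 to 1837. Reordering ignores the dependence of neighboring peaks, so any local correlation lowers the observed count. Chromosome 18 had 41.8% of its peaks raised and 6.31% lowered, and chromosome X 46.0% and 3.13%. The shares of chromosome X rest on 831 merged peaks, since 138 Mb of it lay in stretches without any. Chromosome 11 was balanced, with 19.4% raised and 20.3% lowered and a median log2 fold change of -0.05, below the genome median. Chromosome 5 had 24.7% raised and 19.2% lowered.

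The windows with the highest and lowest medians moved to differing extents. On chromosome 8 from 29 to 30 Mb, 54 of 60 peaks were raised and none lowered, with a median log2 fold change of 3.72 (quartiles 2.73 and 4.48). Chromosome 6 from 19 to 20 Mb had 14 of 16 peaks raised (median 3.14), and chromosome 12 from 79 to 80 Mb had 28 of 33 raised (median 3.02). On chromosome 8, the windows from 53 to 54 Mb and from 78 to 79 Mb had 12 of 19 and 33 of 42 peaks raised (medians 3.17 and 3.04). The lowest window was on chromosome 3 from 92 to 93 Mb, where 22 of 25 peaks were lowered and none raised (median -2.74), followed by its neighbor from 93 to 94 Mb with 13 of 20 lowered (median -2.29). Chromosome 5 from 63 to 64 Mb had 8 of 16 lowered and 1 raised (median -1.84). Chromosome 8 had 13 of 27 lowered from 102 to 103 Mb (median -1.78) and 7 of 22 from 101 to 102 Mb (median -1.50). The planned circular-shift test called 0 windows in either comparison, while 116 CMV and 121 CGRP windows had an unadjusted p under 0.05. That test also recovered 0% of 10 simulated windows, so its count carries no information on these windows. Random reordering, chosen after the data were seen and blind to the dependence of neighboring peaks, called 558 higher and 525 lower CMV windows.

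Amplification and tissue were not separate in the CMV groups: 6 of the 8 amplified libraries were metastases (5 liver, 1 lymph node), and all 7 others were lung tumors. The libraries may also share animals, since 11 of the 15 titles carry a single code and the labels do not say what the code or a final A or B marks; p-values then measure the spread between libraries, which may be technical.

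In CGRP tumors, liver metastases differed little from lung tumors, and mainly by loss. Of 105121 peaks with an adjusted p, 819 (0.779%) were less accessible in liver metastases and 79 (0.0752%) more accessible, from the authors' deposited table. Lowered peaks had a median log2 fold change of -1.65 (median SE 0.39), and raised peaks 1.18 (median SE 0.31). The median over all peaks was 0.01. Against an absolute log2 fold change of 0.5, 66 peaks were lowered and 0 raised in the second deposited test, while 10955 peaks of the first test had an unadjusted p under 0.05. At a peak of median SE (0.52), changes under about 1.03 on the log2 scale could not be told from 0 even before adjustment.

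The most strongly lowered CGRP site lay on chromosome 11 from 9588882 to 9589382, where the authors' deposited table gave -5.44 (SE 0.65, adjusted p = 7.264e-12). The same peak had -4.92 (SE 0.68, adjusted p = 1.395e-10) in the CMV comparison of the authors' deposited table. Its megabase, from 9 to 10 Mb, held 7 lowered peaks among 26. The other 4 leading losses were on chromosome 1 from 125090567 to 125091067 (-4.60, SE 0.58), chromosome 15 from 25905504 to 25906004 (-4.27, SE 0.62), chromosome 1 from 51571057 to 51571557 (-4.22, SE 0.53) and chromosome 6 from 43411940 to 43412440 (-3.95, SE 0.51) in the authors' deposited table. All 5 were also lowered in Nfib-amplified CMV libraries, with log2 fold changes from -4.92 to -2.33 in the authors' deposited table.

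Raised CGRP sites were weaker in effect. The leading one was on chromosome 6 from 58581573 to 58582073, at 3.38 (SE 0.77, adjusted p = 0.00455) in the authors' deposited table. Chromosome 16 from 51047951 to 51048451 followed at 2.23 (SE 0.57), and chromosome 13 from 27024626 to 27025126 at 2.19 (SE 0.60), in the authors' deposited table. These 3 were also raised in the CMV comparison, at 2.65, 2.07 and 1.74 in the authors' deposited table. The remaining pair, on chromosome 2 from 109518070 to 109518570 (2.03, SE 0.46) and chromosome 9 from 92432943 to 92433443 (1.84, SE 0.51), had 0.70 and -0.56 in the CMV comparison of the authors' deposited table, neither past the threshold.

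Chromosome 5 held 24 of the 79 raised CGRP peaks (30.4%) but 5.88% of all peaks, and 20 of the 24 lay beyond 130 Mb. There, the 384 peaks with a mean count of at least 50 had a median log2 fold change of 0.34 (quartiles 0.19 and 0.47), and 91.1% were above 0. The corresponding median on the rest of chromosome 5 was -0.06, and on other chromosomes -0.03. In the CMV comparison the same 384 peaks had a median of -0.61. Peaks of that mean count had -0.18 on the rest of chromosome 5 and 0.08 on other chromosomes. This stretch was chosen after its values were seen.

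By window, the highest CGRP medians were on chromosome 14 from 95 to 96 Mb (1.18), chromosome 5 from 10 to 11 Mb (1.08), chromosome 11 from 110 to 111 Mb (0.97), chromosome 15 from 70 to 71 Mb (0.97) and chromosome 1 from 98 to 99 Mb (0.90). The lowest were on chromosome 4 from 37 to 38 Mb (-0.93), chromosome 14 from 115 to 116 Mb (-0.81) and from 90 to 91 Mb (-0.67), chromosome 3 from 61 to 62 Mb (-0.64) and chromosome 11 from 9 to 10 Mb (-0.63). Few of their peaks passed the threshold: each of the highest windows held at most 1 raised peak. Of the lowest, chromosome 11 had 7 of 26 peaks lowered, chromosome 14 from 115 Mb had 3 of 43, and the others had 0. The 10 peaks on chromosome 14 from 90 Mb had quartiles of -0.89 and 1.03. Within-batch values could not be computed: all 7 liver metastases were prepared in batch 2, as were 7 lung tumors, while the other 4 lung tumors were prepared in batch 3. The titles of the 7 liver metastases carry 3 codes and those of the 11 lung tumors 5 codes, with 9 distinct titles without a final A or B, so libraries here may also share animals or tumors. Of the 11 CGRP lung tumors, 1 was labelled Nfib-amplified and, unlike the amplified CMV libraries, hypoaccessible.

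The comparisons were set against each other to ask whether the same sites changed in both models. Of the 819 sites lost in CGRP liver metastases, 383 (46.8%) were also lost in Nfib-amplified CMV libraries, against 13.1% of all peaks tested in both (odds ratio 5.95, Fisher's exact test, adjusted p = 1.34e-121). Another 83 (10.1%) were raised there, against 35.6% of all peaks (odds ratio 0.202). Raised CMV peaks held a CGRP-pool summit in 54.6% of cases, against 88.2% of unchanged peaks of like mean count. A loss in CGRP libraries could thus be called at fewer of them, which may lower this share. Of 79 sites gained in CGRP metastases, 20 were raised in both, where independent lists would share 28.1 (odds ratio 0.614, adjusted p = 0.0601). Another 18 of the 79 (22.8%, against 13.1% of all peaks) were lowered in the CMV comparison (odds ratio 1.95, adjusted p = 0.0241). Without chromosome 5, left out after the data were seen, 5 of 55 remained (odds ratio 0.690, p = 0.545), and with centring the odds ratio was 1.12 (p = 0.685). With both comparisons centred on their medians, 557 of 863 lowered CGRP peaks were lowered in both (odds ratio 5.39). Peaks are not independent replicates, so these p-values describe the lists.

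**Figure D2:**
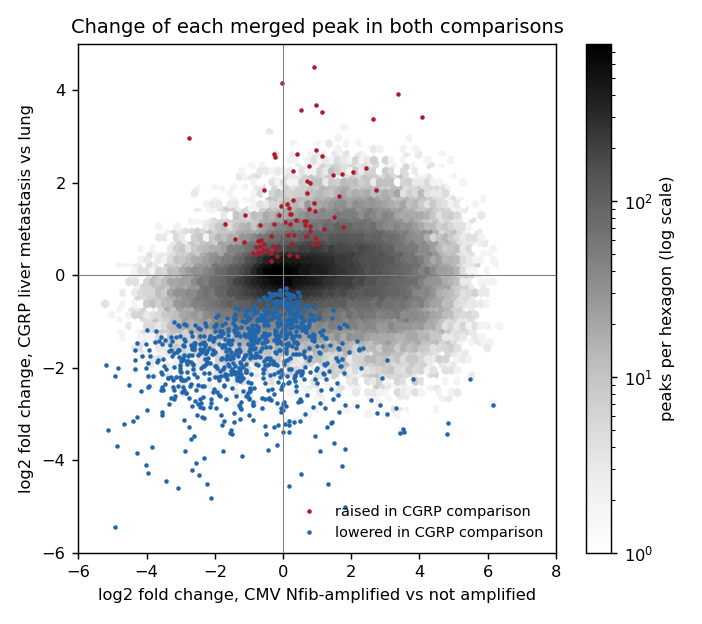
Log2 fold change of each tested merged peak in the CMV comparison (x axis) and the CGRP comparison (y axis). Hexagons are shaded by the number of peaks on a log scale, and points mark the 79 raised (red) and 819 lowered (blue) CGRP peaks, of which 69.5% of the lowered lie left of 0 on the x axis.

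Across all peaks, the log2 fold changes of the comparisons were weakly correlated, with Pearson's r = 0.154 (95% block bootstrap interval 0.141 to 0.167) and Spearman's rho = 0.172. Error in the CGRP values lowers this correlation, which the interval does not cover. Their SD beyond the SE was at most 0.35 in any decile of mean count, against a median SE of 0.52. A z test of the difference called 26660 of 113873 peaks (23.4%), of which 20259 had the higher change in the CMV comparison and 6401 in the CGRP comparison. Centring each comparison on its median turned that split, to 36.5% with the higher change in the CMV comparison. Of the differing peaks, 25106 were themselves changed in the CMV comparison in the same direction as the difference, and 366 were changed in the CGRP comparison.

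Sites gained with Nfib amplification held a summit of the CGRP pool, which joins 14 CGRP libraries, in 54.6% of cases, against 82.9% of unchanged peaks (crude odds ratio 0.249). Sites lost with amplification held one in 97.9% (crude odds ratio 9.56). Within deciles of mean count the odds ratios were 0.082 (95% interval 0.079 to 0.086) and 3.44 (3.04 to 3.90). Both directions are in part built in, since the mean count includes the CGRP libraries: at a given mean, a peak raised in amplified CMV libraries is lower in the rest. The CMV pool of 19 libraries had a summit in 96.5% of raised and 75.2% of lowered peaks. That is no separate evidence, since each merged peak needs a summit in some pool and the CMV pool holds libraries of the comparison. Of the 819 CGRP losses, 94.6% held a CGRP summit, and of the 79 CGRP gains 94.9%, against 85.3% and 84.5% of matched unchanged peaks. These shares are no separate evidence either, since the CGRP pool is made of libraries of that comparison. A CMV summit was held by 77.7% of the losses and 92.4% of the gains, against 92.7% and 92.1%. The CMV pool holds 15 libraries marked low in enrichment, and vector and preparation batch cannot be told apart between these pools.

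**Figure D3:**
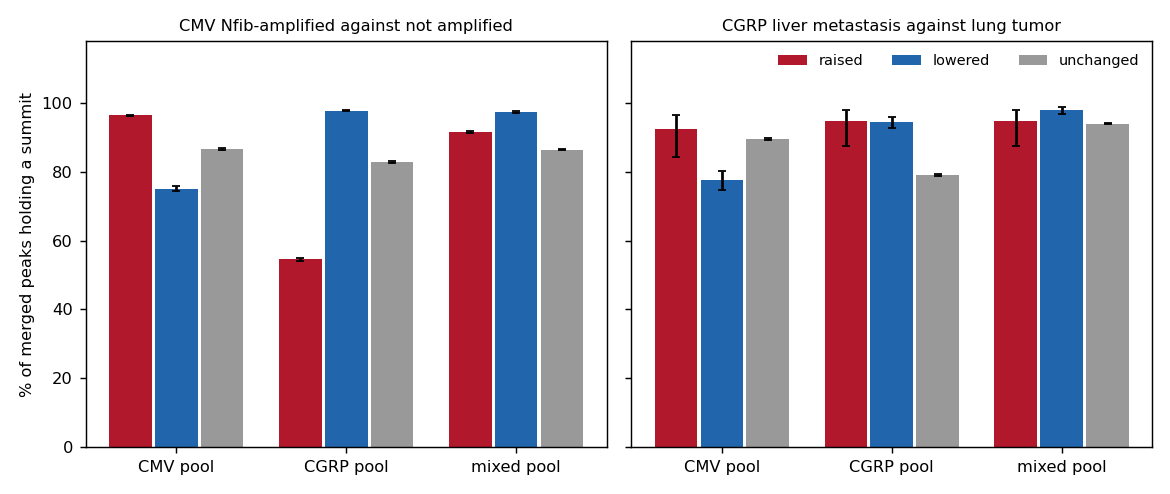
Percent of raised (red), lowered (blue) and unchanged (grey) merged peaks that hold a summit of each pool of libraries, for the CMV comparison (left) and the CGRP comparison (right). Error bars are 95% Wilson intervals for counting error; raised CMV peaks held a CGRP-pool summit in 54.6% of cases and lowered ones in 97.9%.

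The CMV and CGRP pools shared many sites. Of 251512 CMV-pool summits, 125512 (49.9%, 95% Wilson interval 49.7% to 50.1%) lay within 250 bp of a CGRP-pool summit. Of 172434 CGRP-pool summits, 122963 (71.3%, 71.1% to 71.5%) lay near a CMV-pool summit. The gap between these shares went with the lengths of the lists: among the top 100000 summits of each pool by score, the shares were 65.1% and 64.5%. The mixed pool of 11 CMV and 4 CGRP libraries had 206478 summits, 76.6% of them near a CMV-pool summit and 68.7% near a CGRP-pool summit. Of the merged peaks, 73872 (64.8%) held a summit of all 3 pools, 25829 held a CMV but no CGRP summit, and 10375 a CGRP but no CMV summit. These intervals cover counting error only.

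Whole stretches of chromosomes had summits in every pool but no merged peak. There were 58 such stretches with at least 50 summits of each pool, covering 621 Mb. Chromosome 4, which carries Nfib, had 105 Mb in 8 stretches that held 75.3% of its CMV-pool summits, and chromosome 19 had 53.4 Mb in 2 stretches with 86.2%. Chromosome X had 138 Mb in 3 stretches with 67.2%. On chromosome 4 the longest ran from 97989382 to 148000815 and the next from 65998904 to 92063365. The comparisons above therefore say nothing about these stretches.

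**Figure D4:**
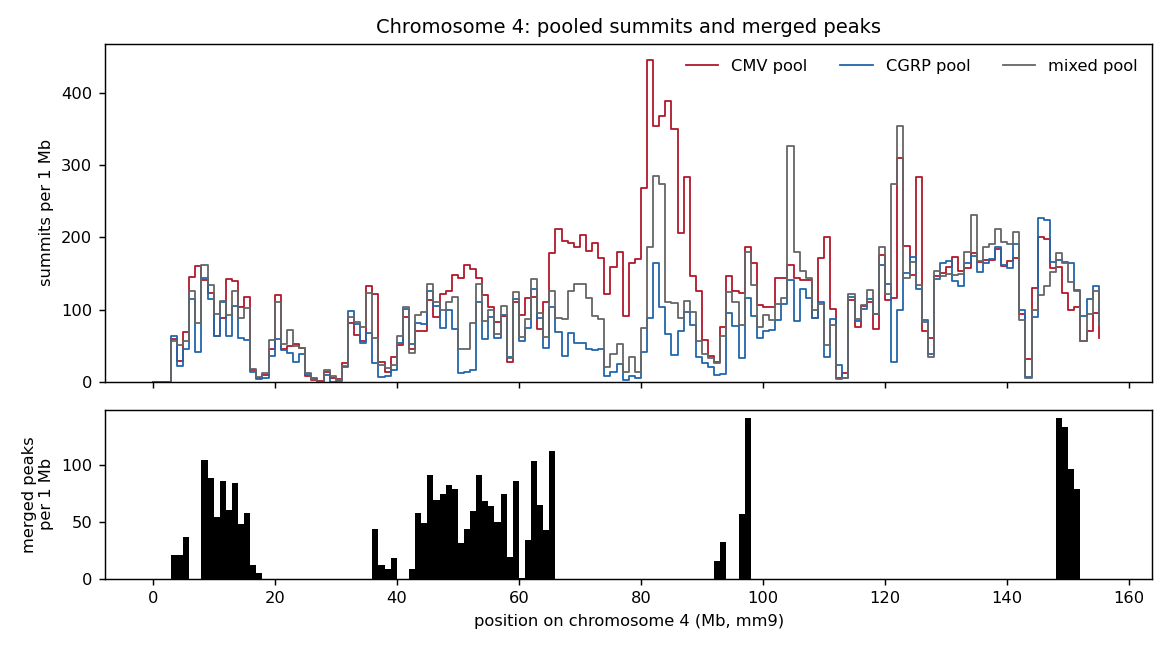
Chromosome 4 (mm9) in windows of 1 Mb: upper panel, summits per window in the CMV (red), CGRP (blue) and mixed (grey) pools; lower panel, merged peaks per window. CMV-pool summits reach 445 in the window from 81 to 82 Mb, where the CGRP pool has 88 and no merged peak was kept.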

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

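Tests chosen only after the result was seen are the span over deciles, the spread beyond the SE, the share of variance within windows, the CMV median of lowered CGRP peaks, the ratio of summits in windows left out to windows kept, and the width between percentiles of the pool ratio. A search for single libraries far from their group was not possible without values per library.

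A difference between groups was found for 26660 peaks, whose log2 fold change differed between the CMV and CGRP comparisons by the z test. The contrasts are not alike, since one sets amplification and the other tissue.

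Raised peaks outnumbered lowered ones 2.80 to 1 in the CMV comparison. A single offset in the size factors would move all deciles of mean count alike, but their medians spanned 1.14 on the log2 scale (interval 1.12 to 1.18). Part of this span is built in, because a peak raised only in amplified libraries has a low mean count. A background raised evenly would move peaks of like strength together, yet their SD beyond the SE was at least 0.93 in each of the 5 lowest deciles. That SD also holds differences between sites that arise with or without such a background, and the SE rests on libraries that may share animals. Copy number of whole regions would place most variance between windows, whereas 76.9% (95% interval 75.8 to 78.1) of the variance beyond the SE lay within 1 Mb windows. Changes of single sites add to that share whatever sets the majority of raised peaks. None of the 3 alone would give this spread of changes among peaks of like strength and within windows. The tests do not decide how far each of them adds to the majority of raised peaks. How far the authors' scaling sets that majority is not settled. A difference in enrichment between libraries and an effect of amplification or metastasis, which the design does not separate, stay open.

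Sites lost in CGRP metastases were often lost in Nfib-amplified CMV libraries. Mean count alone does not account for this overlap, since the odds ratio within 20 strata of mean count was 4.82 (95% interval 4.20 to 5.54). The mean count is averaged over the libraries of both comparisons, so the strata do not equalise strength in the CGRP libraries. Lowered CMV peaks held a CGRP-pool summit in 97.9% of cases, against 94.0% of unchanged peaks of like mean count. Strength in the CGRP libraries therefore stays open as a part of the overlap. Loss of lung cells outside the lung would lower the same sites in both comparisons, because 6 of 8 amplified libraries are metastases. The median CMV log2 fold change of the 819 sites was -0.81 (bootstrap interval -0.94 to -0.61), which is also what a change shared by metastases would give. The 2 readings cannot be told apart here, since no gene or cell type was assigned to the sites.

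Signal in data outside the comparisons came from the stretches without merged peaks, which held 43790 CMV-pool, 32253 CGRP-pool and 38142 mixed-pool summits (17.4%, 18.7% and 18.5% of each pool). In the region of chromosome 4 from 80 to 86 Mb, the CMV pool had 2172 summits and the CGRP pool 501, a ratio of 4.34 against 1.46 genome-wide. The region holds the 5 densest windows of the CMV pool, so a high ratio follows in part from the choice. That pool joins 2 compared and 6 low-enrichment libraries labelled Nfib-amplified, and Nfib lies on this chromosome. Whether copy number sets the ratio was not tested.

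Peak-poor sequence was not settled as the reason for these stretches: windows without merged peaks held 0.802 times the CMV-pool summits of those kept (interval 0.723 to 0.853) where each pool had at least 20 summits, a minimum that itself removes peak-poor windows, and 0.532 times (0.473 to 0.593) without that minimum. Removal of regions whose copy number differs between tumors would spread the log2 ratio of CMV-pool to CGRP-pool summits. Its interquartile range was 0.859 times as wide in windows left out as in windows kept (interval 0.699 to 1.00), and the width from the 5th to the 95th percentile 1.02 times (0.929 to 1.11), both below the bound of 1.2 set beforehand for the first. In the windows kept, however, that ratio went with the median CMV log2 fold change (Spearman's rho = 0.848 over 1695 windows). Its width there thus already holds whatever moves the CMV log2 fold changes, be it accessibility or copy number. The comparison of widths therefore does not decide on copy number that sets the CMV and CGRP pools apart. Copy number that differs among tumors of a pool was not tested, and no biological explanation was tested.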

How the results depend on the processing

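Tests chosen after the data were seen are the second deposited test, the CGRP count without chromosome 5, the reordering of peaks, centring for the overlaps and pools, and the overlap without chromosome 5. Of 137 alternative values for 27 results, 94 were counted as the same, 35 moved, 2 lost the threshold and 6 reversed. For odds ratios of overlaps and pools, the same meant an unchanged direction and side of the threshold, with no limit on size. Thus the odds ratio of 0.202 for peaks lowered in CGRP and raised in CMV counted as the same at 0.734 among the top 5000 peaks (Fisher's exact test, p = 3.72e-05). CMV counts (raised, lowered, changed) were 4247, 1785 and 6032 with Bonferroni adjustment, 15251, 4703 and 19954 without shifted windows, and 21603, 5280 and 26883 in the second deposited test; a mean count minimum of 20 gave 20735 raised and 31386 changed, fewer peaks being tested. Centring gave 22710 raised and 29095 lowered, a share raised of 43.8% against 73.7%. It also turned the share of differing peaks with the higher CMV change to 36.5%. Both shifts arise in part by construction. CGRP counts (raised, lowered, changed) were 230, 1331 and 1561 at an adjusted p under 0.1, 16, 373 and 389 under 0.01, 1, 107 and 108 with Bonferroni adjustment, and 0, 66 and 66 in the second deposited test; 49 raised peaks changed at least 2-fold. The overlap of raised peaks reversed to an odds ratio of 1.10 among the top 5000 peaks (p = 0.134), with 0.614 as the main value, neither past the threshold, and the cause was not tested. The odds ratio of 1.95 for peaks raised in CGRP and lowered in CMV fell to 1.34 at an adjusted p under 0.1 (p = 0.0847) and 1.12 with centring. It turned to 0.476 among the top 5000 peaks (Fisher's exact test, p = 1.01e-18) and to 0.690 without chromosome 5, which held 13 of the 18 shared peaks. The correlation rose to 0.202 among stronger peaks. Reordering called 1083 CMV and 452 CGRP windows against 0 by circular shifts, which had no power in simulation. Shared CMV summits were 43.5% at 100 bp, 53.4% at 500 bp and 65.1% among the top 100000, and shared CGRP summits 63.2%, 75.04% and 64.5%. For raised CGRP peaks in the CMV pool the odds ratio turned from 1.05 to 0.983 with the top 100000 summits, both intervals spanning 1; the cause was not tested. Gene lists and promoter alternatives were not run, nor were refits that need counts, such as leaving out a library. Other splits of the samples could not be counted for the same reason. No paired analysis was possible because the tables hold no values per library. Depth per library is unknown; the median SE was 0.59 (CMV) and 0.52 (CGRP).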

Other observations

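The densest windows of summits lay on chromosome 4, in stretches without merged peaks. The 5 densest windows of the CMV pool ran from 81 to 86 Mb, with 445, 354, 368, 388 and 349 summits per 1 Mb in order of position, where the median window of that pool held 98. The CGRP pool had 88, 165, 103, 66 and 37 summits in the same windows, with a median of 65. The mixed pool was densest on chromosome 4 from 122 to 123 Mb (354 summits) and from 104 to 105 Mb (326), where the CGRP pool had 100 and 141. The CGRP pool itself was densest on chromosome 4 from 145 to 146 Mb (226) and from 146 to 147 Mb (224), followed by chromosome 10 from 80 to 81 Mb (201), which kept 142 merged peaks.

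Chromosome 9 had the highest median CGRP log2 fold change of the chromosomes with at least 200 peaks, at 0.20, with 9 raised and 20 lowered peaks. Chromosome 12 had the highest share of lowered CGRP peaks among the autosomes, 1.11%, and its median was -0.08.

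Of 108 ends of the stretches without merged peaks, 75 lay within 100 kb of a whole megabase, against 20.1% of all merged peaks.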
